A study of Mus musculus with 8 samples.

How the data were processed

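RNA of colon intestinal epithelial cells from 4 WT and 4 PIM1+/- mouse libraries had been extracted with TRIzol and sequenced on an Illumina NovaSeq instrument, per the labels' protocols and the series' design text. The deposited values were TPM per gene in a single table, quantified with RSEM by the authors per the design text. The submitters' processing notes also name HISAT2, StringTie and edgeR, without versions or roles, and the genome build GRCm38.p6. The annotation release, the strand setting, any filter and the read depth are not given in the sources used here. TPM divides reads by gene length and scales each library to a fixed sum, so a large change in abundant transcripts shifts all other values, and reads shared by near-identical genes are divided by estimation. The values were rounded to hundredths. Every per-sample column was used (0 were left out), matched to its sample by the genotype and replicate number in the labels.

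Log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with a mean-variance trend, two-sided), for 12760 genes with at least 1 TPM in at least 4 of the 8 libraries (a gene low in a single genotype could enter through the other), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design named this test for a table of TPM before the data were examined, along with the gene lists, the rule for named genes and most alternatives. Residual and prior degrees of freedom came to 9.27. Of the listed gene IDs 55227 were found in GENCODE release M21 on GRCm38, which gave coordinates and gene types. Symbols were those of the deposited table.

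The text names Pim1, Pim2 and Pim3, and the 12 genes with the largest log2 fold change in each direction among those past the threshold. The latter had to have a mean of at least 1 TPM and no overlap between genotypes. Predicted gene models, immunoglobulin and T cell receptor segments and sex-linked genes were left out of them. Members of each list with the smallest p are also named, up to 4 where the list passed the camera test below and up to 2 otherwise. The design had set up to 4 for every list. Hoxb7, Hoxa3, Hoxa5, Hoxa7 and the genes named under other observations were chosen after their values were seen. Some genes that the rule takes are not reported here, and they were left out of the search for single libraries that stand apart. Each of 36 lists covered a cell type, pathway or process. The 30 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Prac1 and Ahsp were not matched in the table, and Cyr61 and Ctgf were matched as Ccn1 and Ccn2. Icam1, Slc4a1 and Thy1 are each on more than 1 list.

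Nuclear copies of mitochondrial genes were taken as annotated pseudogenes whose transcripts matched a mitochondrial transcript at 90% identity or more over at least 80% of their length (BLAST+ 2.17.0), which gave 16. Alternatives were limma without the trend, upper quartile scaling, no filter, a mean of at least 5 TPM, a pseudocount of 0.1, the replicate number as a block, a score of non-epithelial markers as a covariate, other thresholds, and leaving out each library in turn. After the data were seen, rescaling without mitochondrial transcripts and nuclear copies, a posterior Hox score as a covariate and an exact permutation test of list means were added. A first comparison of posterior Hox genes with Hoxb genes, chosen with their values in view, was replaced by one with all other tested Hox genes, and tests of a list against all genes were likewise set after values were seen. These first required a list to lie 2 SD of its own offset from all genes (-0.75, SD 0.391, for the posterior Hox list, which missed that bound), and then compared the shift of all genes with the shift to be explained. Tests were checked on simulated data with 200 changed genes in the comparison of PIM1+/- with WT, where 12519 genes were tested. Of 98 genes changed 2-fold 81.6% were called, and of 96 changed 1.5-fold 49.0%. No call had the wrong sign, 7.30% of calls were unchanged genes, and 0 genes were called in a table with no change. Noise was drawn independently for each gene, so the simulated table lacks the correlation between genes of the real one. It therefore does not give the error rate of the real calls. Figures were drawn with matplotlib 3.10.9.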

Results

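RNA from intestinal epithelial cells of the mouse colon, the single cell layer that lines the large bowel, was sequenced in 8 libraries, 4 from wild type (WT) mice and 4 from mice labelled PIM1+/-, both on the C57BL/6J strain. Pim1 is a serine/threonine kinase gene, and PIM1+/- denotes a heterozygous genotype. The values were in TPM, transcript abundances scaled to a fixed sum per library, for 55487 genes, of which 28782 were listed at 0 in every library. Between 12582 and 12850 genes reached 1 TPM in a library. The TPM of the listed genes summed to 990958 to 992187 per library, a scale that keeps no read depth, so the depth behind each value is unknown. Pearson correlations of log2(TPM + 1) across genes ran from 0.976 to 0.983 within a genotype and from 0.946 to 0.972 between genotypes, and no libraries held identical values. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries only. Values are means ± SD over n = 4 libraries per genotype. Log2 fold changes (PIM1+/- over WT, ± SE) are on the log2(TPM + 1) scale, which understates changes of low genes.

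The gene named in the genotype was examined first. Pim1 (ENSMUSG00000024014, chromosome 17, 29490753 to 29496112, GRCm38) measured 8.79, 7.86, 5.72 and 8.83 TPM in WT replicates 1 to 4 and 7.97, 7.23, 5.64 and 5.84 TPM in PIM1+/- replicates 1 to 4. The log2 fold change was -0.19 ± 0.15 (95% interval -0.53 to 0.14, limma adjusted p = 0.411), and the ratio of mean TPM was 0.855 (exact permutation p = 0.286, two-sided, where 4 against 4 libraries allow no p below 0.0286). A halving of the WT mean corresponded to -0.84 on this scale, outside that interval. The structure of the altered allele is not given in the sources used here, and the transcript level did not separate the genotypes, so the libraries are named by their labels. The related kinase genes did not pass the test either, with Pim2 at -0.20 ± 0.13 (adjusted p = 0.325) and Pim3 at -0.06 ± 0.11 (adjusted p = 0.75).

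**Figure D1:**
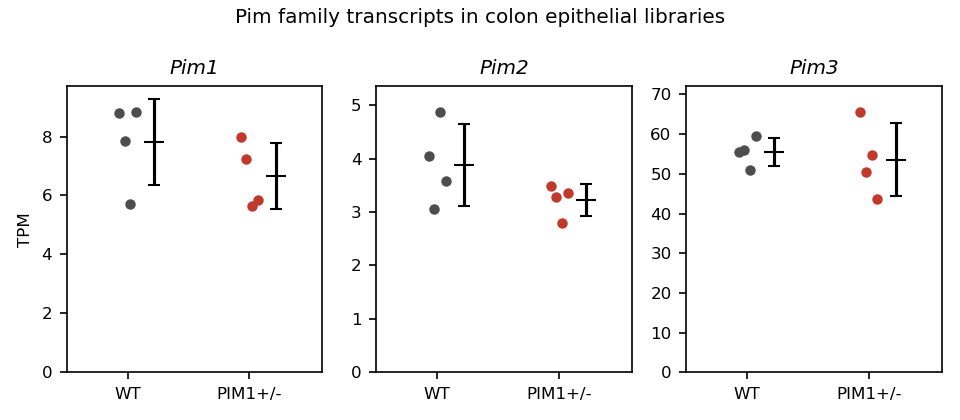
TPM (vertical axes) of Pim1, Pim2 and Pim3 in each library of both genotypes, with points for libraries and black marks for the mean ± SD of 4 libraries. The Pim1 libraries labelled PIM1+/- lie at 5.64 to 7.97 TPM and overlap the WT range of 5.72 to 8.83 TPM.

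The comparison of PIM1+/- with WT libraries asked which transcripts differ in colon epithelium between the genotypes. Interferon-stimulated and antigen presentation genes rose in the libraries labelled PIM1+/-. Ifi27l2a, an interferon-induced gene, went from 2.71 ± 1.71 to 244 ± 109 TPM (log2 fold change 6.10 ± 0.46, adjusted p = 6.53e-05). Cd74, the invariant chain of MHC class II, went from 28.1 ± 25.2 to 696 ± 135 TPM (4.92 ± 0.47, adjusted p = 0.000274). The class II genes H2-Aa, H2-Eb1 and H2-Ab1 rose by 4.66, 4.30 and 4.12. Retnlb, a goblet cell antibacterial protein, rose from 240.0 ± 245 to 2994 ± 1939 TPM (3.91 ± 0.62, adjusted p = 0.00375). Fxyd4, a regulator of the sodium pump, fell (from 43.7 ± 8.5 to 5.71 ± 3.93 TPM, -2.90 ± 0.36). So did the transglutaminase gene Tgm3 (from 385 ± 48.5 to 86.1 ± 42.0 TPM, -2.32 ± 0.39) and the cytokine gene Il18 (from 182 ± 23.9 to 53.3 ± 15.1 TPM, -1.79 ± 0.21).

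Of 12760 genes tested with limma, 2229 passed an adjusted p of 0.05, 1139 higher and 1090 lower in libraries labelled PIM1+/- (51.1% higher), with 219 rising and 136 falling by at least 1 on the log2 scale. The 4 libraries of each genotype did not overlap for 3004 tested genes (23.5%, where chance gives 2.86%). Without WT replicate 4 the number of higher genes was 746, and the number of lower genes was 616 without WT replicate 1, 690 without WT replicate 3 and 689 without WT replicate 4. With values rescaled after leaving out mitochondrial transcripts and their nuclear copies, an alternative chosen after the data were seen, the median log2 fold change of all tested genes moved from -0.01 to -0.11 and the calls to 731 higher and 2215 lower (24.8% higher). A score of non-epithelial cell markers correlated with genotype at 0.933. With it as a covariate limma called 0 genes, with 1059 at an unadjusted p under 0.05 against 4132 without it. With a posterior Hox score as covariate, also chosen after the data were seen, 86 genes were higher and 19 lower. In the gene lists described next, the number of called members moved by more than 1.5 times in 22 of 30 without a filter on low values and in 15 of 29 after that rescaling, and 0 members passed with the non-epithelial covariate. With the posterior Hox covariate 18 interferon, 12 antigen presentation, 1 T and NK cell and 1 myeloid list members rose, 1 mitochondrial transcript fell, and limma called 0 members of the other lists.

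**Figure D2:**
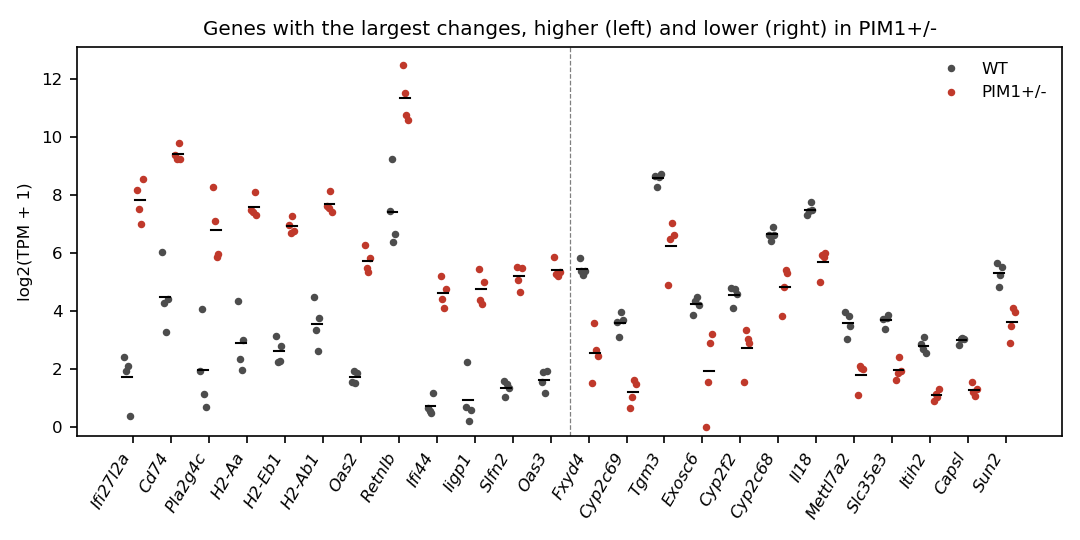
Log2(TPM + 1) (vertical axis) in each library for the 12 genes with the largest increases (left) and the 12 with the largest decreases (right) under the naming rule, with points for libraries and black bars for the mean of 4. Ifi27l2a differs most, at 6.10 on this scale, and Fxyd4 shows the largest decrease, at -2.90.

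All 25 tested type I interferon-stimulated genes rose, and all 25 when adjusted over the list alone. The interferon list had a median of 2.59 (camera adjusted p = 1.58e-31, and adjusted p = 0.206 with an estimated correlation). The 2'-5' oligoadenylate synthetase genes Oas2 and Oas3, sensors of double-stranded RNA, rose by 4.02 ± 0.19 and 3.78 ± 0.20, Rtp4 by 2.95 ± 0.15 and Oasl2 by 3.34 ± 0.18. All 25 tested antigen presentation and interferon-gamma response genes rose too, and all 25 when adjusted over the list alone. The antigen presentation list had a median of 2.07 (camera adjusted p = 3.49e-30, and adjusted p = 0.0763 with an estimated correlation). H2-DMa and H2-DMb1, which load peptides onto class II, rose by 2.91 ± 0.11 and 3.72 ± 0.17, and the class I heavy chain gene H2-D1 went from 442 ± 26.5 to 989 ± 51.6 TPM (1.16 ± 0.06). The other genes with the largest increases were Pla2g4c, a phospholipase A2 gene (4.86 ± 0.75), the interferon-inducible genes Ifi44 (3.90 ± 0.24) and Iigp1 (3.85 ± 0.43), and Slfn2 (3.84 ± 0.20). H2 class I genes share near-identical sequence, so the division of reads among them is uncertain.

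Among markers of T, NK and myeloid cells high enough to test, some rose and none fell. Of 13 tested T, NK and intraepithelial lymphocyte markers 9 rose and none fell, and 12 rose when adjusted over the list alone. The T and NK cell list had a median of 0.88 (camera adjusted p = 3.18e-07, and adjusted p = 0.349 with an estimated correlation). For the T and NK cell list, the median was 1.37 with a pseudocount of 0.1. The granzyme genes Gzmb (from 0.792 ± 0.327 to 6.37 ± 1.26 TPM, 2.04 ± 0.17) and Gzma (from 2.2 ± 0.729 to 11.4 ± 4.34 TPM, 1.92 ± 0.26) encode cytotoxic proteases. The chemokine gene Ccl5 went from 7.19 ± 3.02 to 32.4 ± 16.2 TPM (1.97 ± 0.37). Of 5 tested macrophage, dendritic cell and granulocyte markers 3 rose, and 4 when adjusted over the list alone, among them Mcpt1, a mast cell protease (2.12 ± 0.21), and the complement gene C1qa (1.76 ± 0.37). The myeloid list had a median of 0.79 (camera adjusted p = 0.000871, and adjusted p = 0.206 with an estimated correlation). For the myeloid list, the median was 0.17 without a filter and 2.06 with a pseudocount of 0.1. Over all listed members without a filter, 7 of 20 T and NK cell and 4 of 21 myeloid markers rose. The T and NK cell and myeloid markers are part of the non-epithelial score, and with it as covariate neither list passed (adjusted p = 0.344, median -0.22, and 0.104, median 0.34). Both tested B and plasma cell markers stayed short of the threshold, with Igkc at 0.24 ± 0.39 (adjusted p = 0.712) and Igha at 0.14 ± 0.20 (adjusted p = 0.675). Limma called 0 of them when adjusted over the list alone as well. For the B and plasma cell list, the median was 0.03 without a filter. Of 4 tested fibroblast and matrix genes, Fn1 (1.94 ± 0.28) and Fbln1 (1.46 ± 0.16) rose and Gsn (-0.39 ± 0.08) fell, with 2 and 1 when adjusted over the list alone. For the fibroblast list, the median was 0.02 without a filter. Among 5 smooth muscle genes 0 passed, also when adjusted over the list alone (median 0.04, and -0.07 in the scaling without mitochondrial transcripts, camera adjusted p = 0.524). Of the smooth muscle genes, 1 rose without PIM1+/- replicate 4. For the smooth muscle list, the numbers of members higher and lower were 0 and 1 of 15 without a filter and 0 and 1 with a mean of at least 5 TPM. Its median was -0.13 with the posterior Hox covariate. Both endothelial markers, Vwf (-0.36 ± 0.24, adjusted p = 0.337) and Egfl7 (-0.01 ± 0.14, adjusted p = 0.972), stayed short of it in both adjustments, and no enteric neuron or glia marker was high enough to test. Of 4 red blood cell transcripts 2 rose, and 4 when adjusted over the list alone. Hba-a2 (0.84 ± 0.23) lost its call when single libraries were left out (adjusted p = 0.0715 without WT replicate 1, 0.0813, 0.0633 and 0.0739 without PIM1+/- replicates 1, 2 and 4). Hba-a1 (from 1.39 ± 0.988 to 3.88 ± 1.12 TPM) lost its call too (adjusted p = 0.0583, 0.0869 and 0.0533 without WT replicates 2, 3 and 4, and 0.0695, 0.0855 and 0.0727 without PIM1+/- replicates 2, 3 and 4).

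Epithelial cell markers moved unevenly within their lists. Of 20 absorptive colonocyte markers 9 rose and 1 fell, and 11 and 2 when adjusted over the list alone. The colonocyte list had a median of 0.23 (camera adjusted p = 0.0268, and adjusted p = 0.558 with an estimated correlation). Of the colonocyte genes, 10 rose and 2 fell without WT replicate 2. The colonocyte list did not pass with a mean of at least 5 TPM (adjusted p = 0.0609, median 0.23), with the posterior Hox covariate (0.258, median 0.10), without WT replicate 3 (0.0575), without PIM1+/- replicate 2 (0.104) or without PIM1+/- replicate 3 (0.0701). For the colonocyte list, the numbers of members higher and lower were 4 and 1 without a filter and 7 and 2 in the scaling without mitochondrial transcripts (median 0.12). Its median was 0.45 with the non-epithelial covariate. Emp1 (1.24 ± 0.14) and Tmigd1 (1.07 ± 0.12) rose, while the carbonic anhydrase gene Car4 went from 571 ± 39.5 to 317 ± 34.5 TPM (-0.85 ± 0.08). Of 20 goblet cell markers 8 rose and 4 fell, and 9 and 5 when adjusted over the list alone. The goblet cell list had a median of 0.26 (camera adjusted p = 0.0175, and adjusted p = 0.553 with an estimated correlation). Of the goblet cell genes, 7 rose and 2 fell without WT replicate 3 and 8 rose and 2 fell without PIM1+/- replicate 2 or 3. The goblet cell list did not pass with the non-epithelial covariate (adjusted p = 0.863, median -0.13) or with the posterior Hox covariate (0.369, median 0.04). For the goblet cell list, the numbers of members higher and lower were 7 and 1 without a filter. Its median was 0.16 in the scaling without mitochondrial transcripts. Clca1 went from 1286 ± 488 to 3901 ± 765 TPM (1.65 ± 0.24) and Spink4 from 2056 ± 283 to 5844 ± 1909.5 TPM (1.46 ± 0.20). The kallikrein gene Klk1 fell by 0.51 on the log2 scale. Of 10 tuft cell markers 2 rose, and 2 when adjusted over the list alone. The tuft cell list had a median of 0.31 (camera adjusted p = 0.0233, and adjusted p = 0.553 with an estimated correlation). Of the tuft cell genes, 1 rose without WT replicate 1 or 4 or PIM1+/- replicate 2 and 0 rose without WT replicate 3 or PIM1+/- replicate 1. The tuft cell list did not pass with the non-epithelial covariate (adjusted p = 0.447, median 0.27), with the posterior Hox covariate (0.525, median -0.01), without WT replicate 3 (0.0794) or without PIM1+/- replicate 1 (0.0779). For the tuft cell list, the numbers of members higher and lower were 1 and 0 of 20 without a filter. Its median was 0.51 with a pseudocount of 0.1 and 0.17 without PIM1+/- replicate 1. Of 16 enteroendocrine markers 1 rose, Sct, the secretin gene (1.58 ± 0.37), and 3 fell, and 2 and 4 when adjusted over the list alone (median -0.35, camera adjusted p = 0.0662). Of the enteroendocrine genes, 1 rose and 0 fell without WT replicate 1, 3 or 4 or PIM1+/- replicate 2 and 1 rose and 6 fell without PIM1+/- replicate 4. The enteroendocrine list passed as higher with the posterior Hox covariate (adjusted p = 0.0378, median 0.22). It passed as lower with the non-epithelial covariate (adjusted p = 3.18e-06, median -0.98), without PIM1+/- replicate 3 (0.046) or without PIM1+/- replicate 4 (0.00474). For the enteroendocrine list, the numbers of members higher and lower were 0 and 0 of 20 without a filter. Its median was -0.22 without PIM1+/- replicate 1. Of 15 crypt base stem cell and Wnt target genes 2 rose, among them Cdca7 (0.46 ± 0.08), and 3 fell, among them Rgmb (-0.53 ± 0.11), with the same numbers when adjusted over the list alone. The stem cell median was 0.01, turning to -0.09 in the scaling without mitochondrial transcripts, the mean -0.03, and camera's direction was down (adjusted p = 0.818). Of the stem cell genes, 2 rose and 1 fell without WT replicate 1 or 3 or PIM1+/- replicate 1 or 2. For the stem cell list, the numbers of members higher and lower were 1 and 1 of 20 without a filter. Its median was 0.14 with the posterior Hox covariate and -0.10 without WT replicate 2.

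Mucosal defence and growth genes were also examined. Of 20 antimicrobial and mucosal defence genes 7 rose and 1, Il18, fell, with the same numbers when adjusted over the list alone. The mucosal defence list had a median of 0.32 (camera adjusted p = 0.0107, and adjusted p = 0.507 with an estimated correlation). The mucosal defence list did not pass with the non-epithelial covariate (adjusted p = 0.104, median 0.37), with the posterior Hox covariate (0.726, median -0.06) or without WT replicate 3 (0.0575). For the mucosal defence list, the numbers of members higher and lower were 3 and 1 of 23 without a filter and 7 and 2 in the scaling without mitochondrial transcripts. The lectin gene Itln1 went from 5.72 ± 5.83 to 62.3 ± 39.9 TPM (3.40 ± 0.56). Sprr2a3, which shares sequence with neighbouring Sprr2a copies, went from 382 ± 72.3 to 972 ± 240.0 TPM (1.33 ± 0.17). The peptidoglycan recognition gene Pglyrp1 went from 303 ± 6.24 to 422 ± 25.3 TPM (0.48 ± 0.05). Of 30 DNA replication and mitosis genes 5 rose and 0 fell, also when adjusted over the list alone, among them Mcm3, a subunit of the replicative helicase (0.70 ± 0.15). The replication and mitosis list had a median of 0.27 (camera adjusted p = 0.000634, and adjusted p = 0.624 with an estimated correlation). Of the replication and mitosis genes, 1 rose without WT replicate 1 or 4, 3 rose without WT replicate 2 or PIM1+/- replicate 4 and 2 rose without PIM1+/- replicate 1, 2 or 3. The replication and mitosis list did not pass with the posterior Hox covariate (adjusted p = 0.254, median 0.15). For the replication and mitosis list, the numbers of members higher and lower were 2 and 0 with limma without the trend, 1 and 0 without a filter and 2 and 0 in the scaling without mitochondrial transcripts (median 0.17). Of 25 MYC-induced growth genes 1 rose, and 0 when adjusted over the list alone. The MYC target list had a median of 0.16 (camera adjusted p = 0.0435, and adjusted p = 0.72 with an estimated correlation). Of the MYC target genes, 0 rose and 0 fell without WT replicate 1, 3 or 4 or PIM1+/- replicate 3 or 4, 3 rose and 0 fell without WT replicate 2, 0 rose and 1 fell without PIM1+/- replicate 1 and 2 rose and 0 fell without PIM1+/- replicate 2. The MYC target list did not pass with a mean of at least 5 TPM (adjusted p = 0.0989, median 0.16), with the non-epithelial covariate (0.0621, median 0.22), with the scaling without mitochondrial transcripts (0.063, median 0.05), with the posterior Hox covariate (0.343, median -0.05), without WT replicate 1 (0.0714), without WT replicate 4 (0.222), without PIM1+/- replicate 1 (0.275) or without PIM1+/- replicate 3 (0.0548). For the MYC target list, the numbers of members higher and lower were 0 and 0 with limma without the trend, 0 and 0 without a filter and 0 and 2 in the scaling without mitochondrial transcripts. Its median was 0.07 without PIM1+/- replicate 1.

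Part of the salt transport genes and most tested posterior Hox genes fell. Of 23 colonic salt, water and short-chain fatty acid transport genes 11 fell and 0 rose, and 13 fell when adjusted over the list alone. The transport list had a median of -0.30 (camera adjusted p = 0.000476, and adjusted p = 0.458 with an estimated correlation). Of the transport genes, 0 rose and 7 fell without WT replicate 1, 2, 3 or 4 or PIM1+/- replicate 1 or 3 and 2 rose and 8 fell without PIM1+/- replicate 4. The transport list did not pass with the non-epithelial covariate (adjusted p = 0.777, median -0.10). For the transport list, the numbers of members higher and lower were 0 and 6 of 24 without a filter. Its median was -0.14 with the posterior Hox covariate. The amino acid transporter gene Slc6a14 (-0.69 ± 0.09), Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids (-0.65 ± 0.10), the chloride channel gene Ano1 (-0.90 ± 0.15) and the epithelial sodium channel gene Scnn1a (-0.46 ± 0.09) were among the transport genes that fell. Of 6 tested posterior Hox genes, which mark the distal colon, 4 fell and 0 rose, and 5 fell when adjusted over the list alone. The posterior Hox list had a median of -0.75 (camera adjusted p = 0.00673, and adjusted p = 0.507 with an estimated correlation). Of the posterior Hox genes, 2 fell without WT replicate 1 or PIM1+/- replicate 2 and 1 fell without WT replicate 3 or 4. For the posterior Hox list, the numbers of members higher and lower were 0 and 1 of 10 without a filter. Hoxb13 went from 118 ± 14.7 to 50.3 ± 15.9 TPM (-1.27 ± 0.24, adjusted p = 0.00746). Hoxd13 (-1.10 ± 0.28), Hoxa10 (-0.75 ± 0.18) and Hoxa13 (-0.74 ± 0.19) lost their calls when single libraries were left out. The adjusted p of Hoxd13 was 0.0695, 0.073, 0.0607 and 0.0553 without WT replicates 1, 3 and 4 and PIM1+/- replicate 2. Without the same libraries that of Hoxa10 was 0.0527, 0.0567, 0.050 and 0.0502. For Hoxa13 it was 0.050, 0.0697 and 0.0557 without WT replicates 2, 3 and 4. Of 13 small intestinal enterocyte and Paneth cell genes 3 rose, among them Alpi, intestinal alkaline phosphatase (0.88 ± 0.16), and Ada (0.60 ± 0.11), and 1 fell, with the same numbers when adjusted over the list alone. The small intestinal median was -0.08, the mean 0.05 and camera's direction up (adjusted p = 0.995), turning to down with upper quartile scaling. Of the small intestinal genes, 3 rose and 2 fell without PIM1+/- replicate 3. For the small intestinal list, the numbers of members higher and lower were 3 and 3 in the scaling without mitochondrial transcripts. Its median was 0.03 without a filter.

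**Figure D3:**
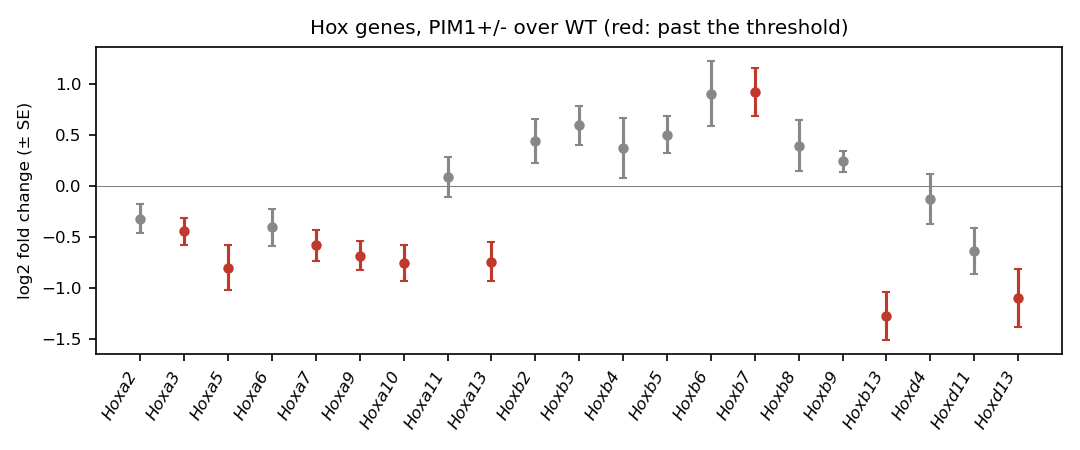
Log2 fold change ± SE (vertical axis, PIM1+/- over WT, 4 libraries each) of the tested Hox genes, with red points for an adjusted p under 0.05. Hoxb13 lies lowest, at -1.27, and Hoxb7 highest, at 0.92.

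The other genes with the largest decreases included the cytochrome P450 genes Cyp2c69 (-2.39 ± 0.24), Cyp2f2 (-1.85 ± 0.35) and Cyp2c68 (-1.80 ± 0.30), of a family with near-identical members, and Mettl7a2 (-1.77 ± 0.27), Slc35e3 (-1.72 ± 0.17), Itih2 (-1.71 ± 0.14), Capsl (-1.71 ± 0.13) and Sun2, a nuclear envelope gene (-1.70 ± 0.27). Exosc6, a subunit of the RNA exosome, was listed at 13.5, 19.6, 21.3 and 17.8 TPM in WT replicates 1 to 4 and at 0, 1.96, 6.48 and 8.30 TPM in PIM1+/- replicates 1 to 4 (-2.31 ± 0.60, adjusted p = 0.0298). Its call was lost without WT replicate 1 (adjusted p = 0.0556), 2 (0.0592), 3 (0.0722) or 4 (0.0682) or PIM1+/- replicate 2 (0.0719).

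Most tested mitochondrially encoded transcripts fell. Of 10 tested members 8 fell and 0 rose, and 10 fell when adjusted over the list alone. The mitochondrial list had a median of -0.40 (camera adjusted p = 2.19e-06, and adjusted p = 0.253 with an estimated correlation). For the mitochondrial list, the numbers of members higher and lower were 0 and 2 of 11 without a filter. The cytochrome b gene mt-Cytb went from 13403 ± 543 to 9773 ± 751 TPM (-0.46 ± 0.07) and the complex I gene mt-Nd2 from 3263 ± 106 to 2397 ± 163 TPM (-0.45 ± 0.06). Mitochondrial transcripts took 16.1% to 18.4% of TPM in WT and 12.5% to 13.7% in PIM1+/- libraries. Together with their nuclear copies they took 27.1% to 30.4% in WT and 20.9% to 23.5% in PIM1+/- libraries. A single gene, mt-Atp8, had the highest mean of the list, at 83232 ± 5907 TPM in WT and 63594 ± 2032 TPM in PIM1+/- libraries. Of the 13 listed genes only the 10 tested reached the filter. Of 35 nuclear-encoded oxidative phosphorylation genes 14 rose and 0 fell, and 21 rose when adjusted over the list alone. The oxidative phosphorylation list had a median of 0.14 (camera adjusted p = 3.18e-07, and adjusted p = 0.246 with an estimated correlation). Of the oxidative phosphorylation genes, 7 rose without WT replicate 3 or PIM1+/- replicate 4, 6 rose without WT replicate 4 or PIM1+/- replicate 3, 9 rose without PIM1+/- replicate 1 and 8 rose without PIM1+/- replicate 2. The oxidative phosphorylation list did not pass with the non-epithelial covariate (adjusted p = 0.0501, median 0.07). For the oxidative phosphorylation list, the numbers of members higher and lower were 5 and 0 with limma without the trend, 9 and 0 without a filter and 2 and 0 in the scaling without mitochondrial transcripts. In the scaling without mitochondrial transcripts the median was 0.03, against -0.11 for all genes. Uqcrq of complex III rose by 0.29 ± 0.05 and Cyc1 by 0.26 ± 0.05. Of 20 glycolysis genes 9 rose and 1 fell, and 10 and 1 when adjusted over the list alone. The glycolysis list had a median of 0.26 (camera adjusted p = 0.000446, and adjusted p = 0.439 with an estimated correlation), with the lactate transporter gene Slc16a3 at 1.40 ± 0.27 and Eno1 at 0.44 ± 0.06. Of the glycolysis genes, 6 rose and 0 fell without WT replicate 1 or 4 or PIM1+/- replicate 2, 7 rose and 0 fell without PIM1+/- replicate 3 and 8 rose and 0 fell without PIM1+/- replicate 4. The glycolysis list did not pass with the posterior Hox covariate (adjusted p = 0.117, median 0.12). For the glycolysis list, the numbers of members higher and lower were 6 and 0 without a filter. Its median was 0.40 with the non-epithelial covariate and 0.15 in the scaling without mitochondrial transcripts. Of 23 cholesterol synthesis genes 3 rose and 0 fell, and 10 and 1 when adjusted over the list alone. The cholesterol list had a median of 0.20 (camera adjusted p = 0.000454, and adjusted p = 0.507 with an estimated correlation). Of the cholesterol genes, 2 rose and 1 fell without WT replicate 2, 7 rose and 0 fell without WT replicate 3 and 5 rose and 0 fell without PIM1+/- replicate 2. For the cholesterol list, the numbers of members higher and lower were 7 and 1 with upper quartile scaling and 3 and 1 in the scaling without mitochondrial transcripts (median 0.09). Its median was 0.32 with the non-epithelial covariate. Fdps rose by 0.42 ± 0.08. Of 24 unfolded protein and integrated stress response genes 7 rose and 0 fell, and 12 rose when adjusted over the list alone, including the disulfide isomerase genes Pdia6 (0.63 ± 0.11) and Pdia3 (0.41 ± 0.08). The unfolded protein list had a median of 0.28 (camera adjusted p = 0.000217, and adjusted p = 0.507 with an estimated correlation). Of the unfolded protein genes, 4 rose without WT replicate 1 and 3 rose without WT replicate 3 or 4. The unfolded protein list did not pass with the posterior Hox covariate (adjusted p = 0.794, median just below 0). For the unfolded protein list, the numbers of members higher and lower were 3 and 0 of 25 without a filter and 6 and 1 in the scaling without mitochondrial transcripts (median 0.18). Of 24 fatty acid oxidation and PPAR target genes 2 rose, Pparg (0.85 ± 0.11) and Fabp2 (0.64 ± 0.09), and 3 fell, and 2 and 4 when adjusted over the list alone (median -0.08, camera adjusted p = 0.162). Of the fatty acid oxidation genes, 2 rose and 5 fell without WT replicate 3. The fatty acid oxidation list passed as lower with the non-epithelial covariate (adjusted p = 0.0184, median -0.21) or without WT replicate 3 (0.012). For the fatty acid oxidation list, the numbers of members higher and lower were 2 and 7 in the scaling without mitochondrial transcripts (median -0.19).

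Lists with changes in both directions followed. Of 26 xenobiotic and steroid metabolism genes 6 rose and 5 fell, and 9 and 8 when adjusted over the list alone (median 0.10, turning to -0.01 in the scaling without mitochondrial transcripts, camera adjusted p = 0.643), with Cyp4f14 at 0.64 ± 0.11 and Gstt1 at -0.85 ± 0.12. Of the xenobiotic genes, 4 rose and 3 fell without WT replicate 1 or PIM1+/- replicate 3, 5 rose and 3 fell without WT replicate 3 or 4 or PIM1+/- replicate 4, 3 rose and 3 fell without PIM1+/- replicate 1 and 3 rose and 4 fell without PIM1+/- replicate 2. For the xenobiotic list, the numbers of members higher and lower were 3 and 3 of 32 without a filter and 4 and 8 in the scaling without mitochondrial transcripts. Of 24 NRF2 target and redox genes 4 rose, among them Taldo1 of the pentose phosphate pathway (0.42 ± 0.05), and 5 fell, among them Cbr3 (-0.97 ± 0.11), and 6 and 5 when adjusted over the list alone. The NRF2 median was 0.04, turning to -0.06 in the scaling without mitochondrial transcripts, the mean -0.09, and camera's direction was up (adjusted p = 0.936) where fry's was down. For the NRF2 list, the numbers of members higher and lower were 3 and 8 in the scaling without mitochondrial transcripts. Of 24 tight and adherens junction genes 4 rose, among them Dsc2 (0.47 ± 0.05) and Cldn15 (0.66 ± 0.08), and 2 fell, also when adjusted over the list alone (median 0.02, turning to -0.09 in the same scaling, camera adjusted p = 0.604). Of the junction genes, 2 rose and 1 fell without WT replicate 1, 2 rose and 2 fell without PIM1+/- replicate 1 or 2 and 2 rose and 3 fell without PIM1+/- replicate 3. The junction list passed as higher with the posterior Hox covariate (adjusted p = 0.0268, median 0.10). For the junction list, the numbers of members higher and lower were 2 and 2 with limma without the trend, 2 and 2 of 25 without a filter and 2 and 6 in the scaling without mitochondrial transcripts.

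Death, inflammation and clock genes completed the lists. Of 27 apoptosis, necroptosis and pyroptosis genes 9 rose and 0 fell, and 9 rose when adjusted over the list alone. The cell death list had a median of 0.19 (camera adjusted p = 0.000454, and adjusted p = 0.0763 with an estimated correlation). Of the cell death genes, 5 rose without WT replicate 1 or 4. For the cell death list, the numbers of members higher and lower were 5 and 0 of 29 without a filter. Its median was 0.09 in the scaling without mitochondrial transcripts. The cell death genes that rose included the necroptosis effector gene Mlkl (from 13.5 ± 2.93 to 30.6 ± 4.25 TPM, 1.13 ± 0.14), Bak1 (0.38 ± 0.07) and the gasdermin genes Gsdmc2 (1.44 ± 0.22) and Gsdmc4 (0.91 ± 0.17), near-identical copies whose reads could be divided. Of 13 inflammatory cytokine, chemokine and NF-kB target genes 2 rose, Tnf (0.94 ± 0.21) and Saa3, and 1 fell, and 4 and 3 when adjusted over the list alone (median 0.01, turning to -0.10 in the scaling without mitochondrial transcripts, camera adjusted p = 0.818). Of the inflammation genes, 1 rose and 0 fell without WT replicate 1 or PIM1+/- replicate 2, 1 rose and 3 fell without WT replicate 2 and 3 rose and 0 fell without PIM1+/- replicate 4. For the inflammation list, the numbers of members higher and lower were 2 and 2 with upper quartile scaling, 0 and 0 of 25 without a filter, 1 and 1 with a mean of at least 5 TPM and 2 and 3 in the scaling without mitochondrial transcripts. Its median was -0.13 with the posterior Hox covariate. Saa3 (1.83 ± 0.46) lost its call without WT replicate 1 (adjusted p = 0.0579), 2 (0.0514) or 3 (0.0663) or PIM1+/- replicate 1 (0.0625) or 2 (0.0603). Of 17 STAT3 and STAT5 target genes 1 rose and 1, the survival gene Mcl1 (-0.40 ± 0.06), fell, and 0 and 1 when adjusted over the list alone. The STAT median was 0.08, turning to -0.03 in the same scaling, the mean -0.06, and camera's direction was down (adjusted p = 0.933). Of the STAT target genes, 0 rose and 1 fell without WT replicate 1, 3 or 4 or PIM1+/- replicate 1 or 3 and 0 rose and 2 fell without PIM1+/- replicate 4. For the STAT target list, the numbers of members higher and lower were 2 and 1 with upper quartile scaling, 0 and 1 of 22 without a filter, 0 and 1 with a mean of at least 5 TPM and 0 and 2 in the scaling without mitochondrial transcripts. Its median was -0.10 with the posterior Hox covariate and -0.03 without PIM1+/- replicate 1. Of 16 circadian genes 1 rose and 3 fell, among them Nr1d1 (-0.69 ± 0.15), and 2 and 3 when adjusted over the list alone (median -0.19, camera adjusted p = 0.19). Of the circadian genes, 0 rose and 1 fell without WT replicate 1 or PIM1+/- replicate 1 or 2, 0 rose and 3 fell without WT replicate 2, 0 rose and 2 fell without WT replicate 3 or 4 and 1 rose and 1 fell without PIM1+/- replicate 4. For the circadian list, the numbers of members higher and lower were 0 and 1 of 19 without a filter and 0 and 2 with a mean of at least 5 TPM. Its median was 0.14 with the non-epithelial covariate, -0.30 in the scaling without mitochondrial transcripts and -0.06 without PIM1+/- replicate 4. Of 20 immediate early and heat shock genes, which respond to tissue handling, 1 rose and 6 fell, among them Fosb (-0.54 ± 0.12), and 3 and 9 when adjusted over the list alone. The immediate early list had a median of -0.26 (camera adjusted p = 0.0365, and adjusted p = 0.553 with an estimated correlation). Of the immediate early genes, 0 rose and 1 fell without WT replicate 1, 2 rose and 11 fell without WT replicate 2, 0 rose and 2 fell without WT replicate 3, 1 rose and 2 fell without WT replicate 4 or PIM1+/- replicate 3, 2 rose and 2 fell without PIM1+/- replicate 1, 1 rose and 1 fell without PIM1+/- replicate 2 and 0 rose and 6 fell without PIM1+/- replicate 4. The immediate early list did not pass with a mean of at least 5 TPM (adjusted p = 0.0714, median -0.20), with the non-epithelial covariate (0.0531, median -0.23), with the scaling without mitochondrial transcripts (0.115, median -0.36), with the posterior Hox covariate (0.713, median -0.05), without WT replicate 1 (0.0528), without WT replicate 4 (0.092) or without PIM1+/- replicate 1 (0.0753). For the immediate early list, the numbers of members higher and lower were 0 and 3 with limma without the trend, 0 and 0 of 22 without a filter, 2 and 6 with a mean of at least 5 TPM and 0 and 10 in the scaling without mitochondrial transcripts.

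**Figure D4:**
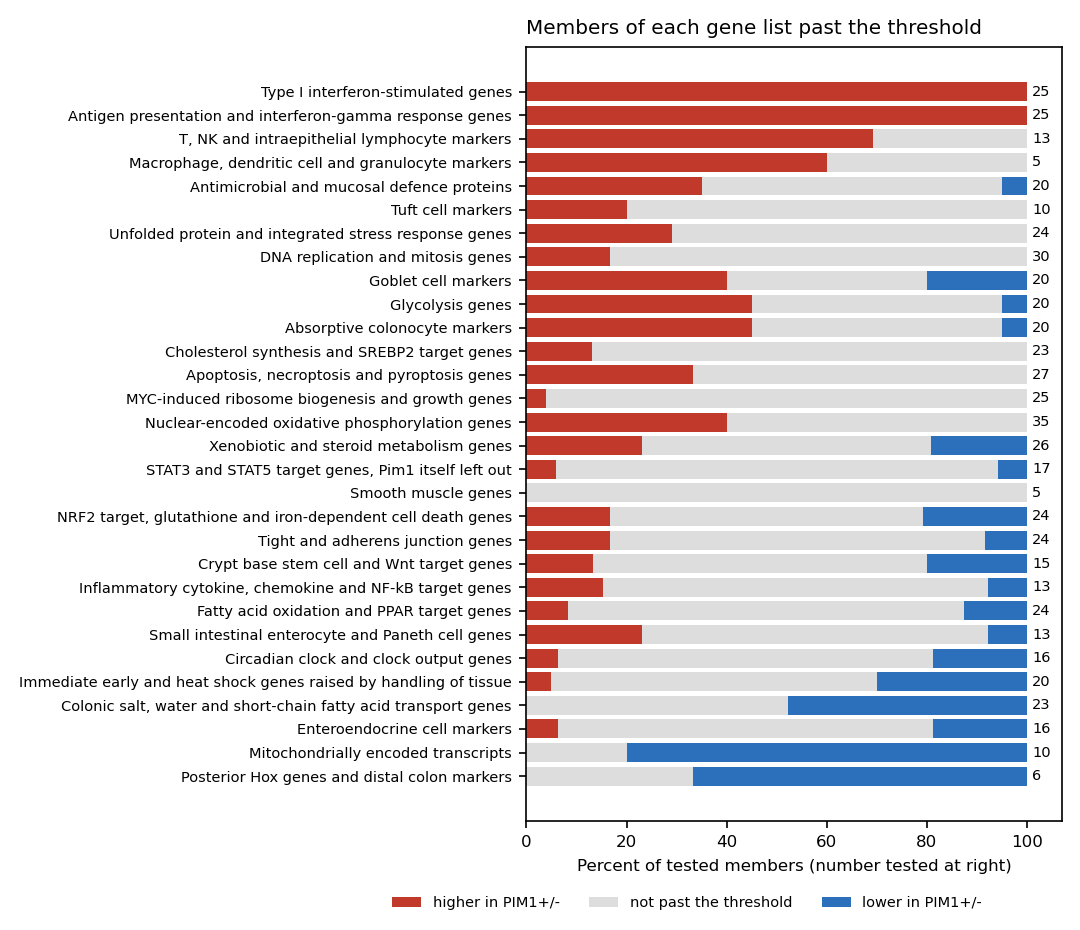
Percent of tested members (horizontal axis) of each of 30 gene lists that were higher, lower or not past an adjusted p of 0.05 over all genes tested, 4 libraries per genotype, with the number tested at the right and lists ordered by median log2 fold change. All 25 tested members of the interferon and of the antigen presentation list were higher; in the scaling without mitochondrial transcripts 2 and not 14 of the 35 oxidative phosphorylation genes were higher, and the medians of the stem cell, inflammation, STAT, junction, NRF2, xenobiotic and smooth muscle lists turned negative.

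Camera with a preset correlation called 15 lists higher and 4 lower of 30 tested, and none of the 19 calls held with an estimated correlation (0 lists, smallest adjusted p = 0.0763, with 5 lists at an unadjusted p under 0.05). Fry, which tests whether the genes of a list move on balance in a single direction without comparing them with other genes, called 7 higher and 2 lower. Xist was listed at 0 to 0.07 TPM and the Y-linked gene Ddx3y at 11.88 to 15.97 TPM across libraries of both genotypes, and limma called 0 of the 4 tested sex-linked genes, over all genes or when adjusted over the list alone.

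Genes close to Pim1 were compared with the rest of the genome. Within 10 Mb of Pim1 on chromosome 17, 80 of 363 tested genes passed the threshold (22.0%), against 2148 of 12391 elsewhere (17.3%, one-sided Fisher exact p = 0.0138). The part of this window that holds the major histocompatibility complex (MHC, 33974659 to 37274484, GRCm38) contained 49 of these genes among 115 tested (42.6%), 44 of them higher, with H2-Aa, H2-Eb1 and H2-Ab1 among them. Without that part 31 of 248 genes passed (12.5%).

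**Figure D5:**
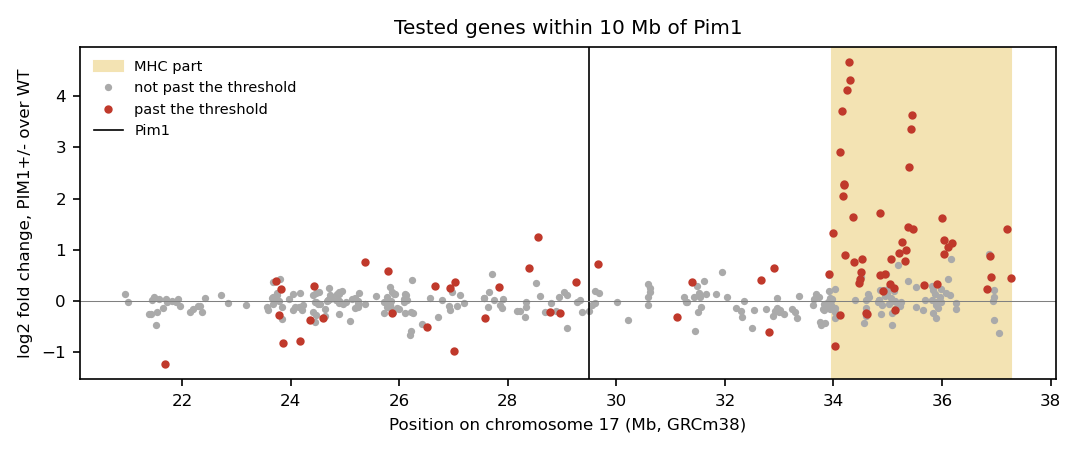
Log2 fold change (vertical axis, PIM1+/- over WT, 4 libraries each) of 363 tested genes by start position on chromosome 17 (horizontal axis, Mb, GRCm38), with red points for an adjusted p under 0.05, a black line at Pim1 and shading over the MHC part. The shaded part holds 49 of the 80 genes past the threshold.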

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

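In this part the tests of members off chromosome 17, of the window without the MHC, of immune marker ratios, of posterior against other Hox genes, of the median of all genes against the Hox list and all those of the mitochondrial list were chosen only after the result was seen. The posterior Hox covariate and the rescaling were added after the data were seen, but before their own results were. The tests with non-epithelial markers as a covariate, of the window around Pim1 and of the library splits were set before.

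Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes as the genotypes, the genotype split itself. It gave 2229 genes, against at most 8 in any other split. That is the strongest outcome 35 splits allow (smallest two-sided exact permutation p = 0.0286). It argues against chance for the gene count without excluding it. Differences between the groups other than genotype were not tested by the splits. For gene lists 1 of 35 splits gave as many calls, again the genotype split. The margin was narrow, with 19 lists against 18 in the highest other split. Every other split gave list calls, from 2 to 18. Where each group of 4 held 2 libraries of each genotype, 2 to 11 lists were called. Camera with the preset correlation thus called lists without a contrast of genotypes, so its list calls alone do not show a genotype difference.

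For the rise of interferon and antigen presentation genes, strain sequence carried along with the altered allele, other cells and a different piece of colon were weighed. Calls were more frequent within 10 Mb of Pim1 than elsewhere (one-sided Fisher exact p = 0.0138, a test set beforehand), as strain sequence predicts. Outside the MHC the share was 12.5% against 17.3% elsewhere, which argues against strain sequence for that part of the window. Of the list members off chromosome 17, 39 of 39 passed and were higher, and they lie outside any sequence carried beside Pim1. This count followed from all 50 members having passed, and an effect on them through genes near Pim1 was not tested. Within the MHC strain sequence stays open. With the posterior Hox score as a covariate 30 of 50 members passed (median log2 fold change 1.86, median SE 0.28, against 2.36 and 0.19 without it). This was more than the prediction for a more proximal piece of colon allowed. The score correlated with genotype at -0.83 and measures the sampling site only indirectly, so a more proximal piece cannot be told apart from genotype. The test set beforehand for more immune or stromal cells came out as that explanation predicts, with 0 of 50 members past the threshold (median 1.94, median SE 0.52), but the score correlated with genotype at 0.933, so the SE grew and this explanation cannot be told apart from genotype. A narrower form, a larger share of immune cells with unchanged RNA per cell, was tested after that result. The members' median log2 ratio exceeded that of 20 immune markers by 1.27 (SD 0.576 over the 4 PIM1+/- libraries). However, 3 of these markers, Mcpt1, C1qa and Gzmb, rose by more than the members' median. Their WT means were low, at 0.54, 0.56 and 0.79 TPM, and they entered the test mainly through the PIM1+/- libraries, so their ratios are uncertain. A larger share of the cells they mark therefore stays open, as do altered expression per cell and genotype.

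For the fall of posterior Hox genes, scaling and a more proximal piece of colon were weighed. A scaling factor common to all genes would have moved them all by about as much. The median of all tested genes lay at -0.0081 on average over the 4 PIM1+/- libraries (SD 0.0328), against -0.75 for the list. That median was known before this comparison was set, so the comparison could not have failed. The bound set first, on the list's own offset from all genes (-0.75, SD 0.391), was missed. No conclusion on a common factor is therefore drawn. The rescaling without mitochondrial transcripts (median -0.86) adds nothing, because the mitochondrial share fell in every PIM1+/- library and the rescaling could only lower other genes. The posterior genes fell relative to the 15 other tested Hox genes (difference -0.80, exact permutation p = 0.0286, the smallest this design allows), but 4 of those, Hoxa3, Hoxa5, Hoxa7 and Hoxa9, also fell, while Hoxb7 rose. A more proximal sampling site therefore cannot be told apart from genotype.

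For the fall of mitochondrial transcripts, a scaling factor common to all genes, reads divided with nuclear copies and handling were weighed. Such a factor would move all genes alike, but the median of all genes lay at -0.0081 on average over the 4 PIM1+/- libraries (SD 0.0328). No shift of the list's size was seen in that median, but the median was known before the comparison was set. The comparison could not have failed, so no conclusion on a common factor is drawn from it. The list lay -0.39 from that median (SD 0.0862), an offset that its camera call already implied. The summed TPM of these transcripts and their nuclear copies also fell (log2 ratio of means -0.32), which argues against divided reads. Handling before extraction, tested by the mean of the immediate early list (difference -0.18, exact permutation p = 0.0857), cannot be told apart from genotype with so few libraries. An effect of genotype was not tested apart from it.

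Single libraries lay far from the other 3 of their genotype in 22 of 314 groups examined, where chance gives about 5%. The count is not far above that share, and the groups are not independent, because the lists hold many of the named genes. Any single entry below can therefore be chance. In WT replicate 1, Car4 (629 against 545 to 559 TPM) and Avil (2.83 against 1.45 to 1.63 TPM) stood apart. WT replicate 2 did so for Pla2g4c (15.7 against 0.62 to 2.86 TPM), Iigp1 (3.7 against 0.16 to 0.60 TPM) and Spink4 (2476 against 1856 to 1952 TPM). WT replicate 3 stood apart for Sct (9.76 against 24.5 to 26.1 TPM) and the mean log2(TPM + 1) of the tuft (1.1 against 1.38 to 1.41) and cholesterol (5.57 against 5.35 to 5.37) lists. In WT replicate 4, Pglyrp1 (293 against 305 to 307 TPM) and the mitochondrial list mean (12.6 against 12.4 to 12.5) differed. PIM1+/- replicate 1 stood apart for Mettl7a2 (1.14 against 2.98 to 3.29 TPM), Alox5ap (4.86 against 1.21 to 1.33 TPM), Nr1d1 (39.3 against 62.7 to 64.3 TPM), mt-Cytb (8650.4 against 10076 to 10219.6 TPM), Hoxb13 (26.6 against 56.7 to 60.5 TPM) and the means of the fatty acid oxidation (5.89 against 5.96 to 5.97) and myeloid (2.68 against 2.49 to 2.5) lists. In PIM1+/- replicate 3 H2-DMa differed (39.4 against 27.7 to 29.5 TPM). PIM1+/- replicate 4 stood apart for Fabp2 (654 against 788 to 811 TPM), Mcpt1 (8.11 against 4.79 to 4.94 TPM), Egfl7 (1.12 against 1.25 to 1.26 TPM) and the colonocyte list mean (7.81 against 8.2 to 8.24).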

How the results depend on the processing

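The rescaling without mitochondrial transcripts, the posterior Hox covariate and the exact permutation of list means were chosen only after the data were seen. Over the alternatives other than leaving out a library, the 128 named genes gave 1124 values. Of these 851 kept their direction and side of the threshold, 254 lost their call, 5 gained a call and 14 reversed. Leaving out 1 library gave 1024 values, of which 914 kept both, 97 lost their call, 7 gained one and 6 reversed. Among the 254 lost calls, 110 came with the non-epithelial covariate, 94 with the posterior Hox covariate and 27 without a filter. Each other alternative lost at most 9. The 14 reversals came from the 2 covariates, 7 from each. Genes higher and lower numbered 773 and 666 without a filter (26705 genes tested), 760 and 689 with the replicate block, 0 and 0 with the non-epithelial covariate, 731 and 2215 after rescaling, 86 and 19 with the posterior Hox covariate, and 219 and 136 with an absolute log2 fold change of at least 1; leaving out 1 library gave 746 to 1004 higher and 616 to 1054 lower. Same-numbered libraries did not deviate together (correlations -0.136, 0.0320, -0.0332 and -0.0710), and 0 of 8 libraries correlated best with their own number, so the numbers were not read as pairs. Lists higher and lower numbered 8 and 4 with the non-epithelial covariate, 9 and 2 with the posterior Hox covariate, 10 and 2 with a mean of at least 5 TPM (26 lists tested, and 3 calls changed), 14 and 2 after rescaling (where the mitochondrial list is left out), 7 and 2 with fry, 0 and 0 with an estimated correlation and 0 and 0 with exact permutation, whose smallest adjusted p was 0.0612 (14 lists at an unadjusted p of 0.0286, the smallest possible). Leaving out 1 library gave 12 to 15 lists higher and 3 to 5 lower. A stricter threshold gives smaller counts by construction. Fewer libraries or more tested genes make calls harder to reach, but whether they account for the smaller counts was not tested. The covariates correlated with genotype at 0.933 and -0.83, and for their effect and the other changes the cause was not tested. The number of called members moved by more than 1.5 times in 22 lists without a filter, 5 without the trend, 3 with upper quartile scaling, 15 after rescaling, 9 with the replicate block and 5 with a mean of at least 5 TPM, and the camera call changed in 11 lists with the non-epithelial and 12 with the posterior Hox covariate.

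With the non-epithelial covariate the log2 fold change reversed for Pim2 (0.20), Tfrc (0.21), Hspa1b (-0.29), Nkg7 (-0.0613), Ccl5 (-0.60), Igha (-0.79) and Vwf (0.19), and with the posterior Hox covariate for Exosc6 (0.26), Alox5ap (-0.62), Igkc (-0.61), Flna (-0.26), Vwf (0.18), Hoxa13 (0.00721) and Hoxd13 (0.14). Leaving out 1 library reversed Igkc (-0.17 to 0.50), Egfl7 (-0.11 to 0.0479), Igha (-0.0030 to 0.33) and Pim3 (-0.16 to 0.0304), none of which passed the threshold with all libraries, and the cause of these reversals was not tested.
DESeq2, limma-voom, count-based scaling and TPM beside counts were not run, because the table analysed here holds no counts. Pim1 stayed short of the threshold in every alternative run, and without counts the depth limits of low genes are unknown.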

Other observations

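The tests in this part were all chosen only after the data were seen: tested genes were grouped by the shared stem of their symbols, and each of 370 families was compared with all other tested genes for calls in each direction (740 Fisher exact tests, adjusted together). Genes are not independent replicates, and neighbouring family members can share reads. All 6 butyrophilin-like (Btnl) genes, a family that shapes intraepithelial gamma-delta T cells and lies beside the class II genes, rose (median log2 fold change 0.66, adjusted p = 5.28e-05), with Btnl2 going from 1.31 ± 0.469 to 6.24 ± 1.59 TPM and Btnl1 from 33.8 ± 6.9 to 56.9 ± 4.43 TPM. Btnl5-ps and Btnl7-ps are among the 6 and carry pseudogene symbols. Most tested Psmd and Psmb proteasome genes rose, not only the immunoproteasome subunits of the antigen presentation list. Of 14 regulatory particle (Psmd) genes 8 rose and 0 fell (median 0.27, adjusted p = 0.000447), Psmd11 at 0.40 ± 0.07 among them, and of 10 Psmb genes 8 rose (adjusted p = 2.78e-05), including Psmb3 (0.39 ± 0.06) and Psmb4 (0.29 ± 0.05), which are outside that list. The medians of the Btnl, Psmd and Psmb families stayed positive with upper quartile scaling and in the scaling without mitochondrial transcripts (0.16 for Psmd).

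Galectin and Clca genes rose in most tested members, and cytochrome P450 genes changed in both directions. Of 8 Lgals genes 5 rose (adjusted p = 0.0115), namely Lgals1, Lgals3, Lgals8, Lgals9, which went from 66.3 ± 11.7 to 344 ± 71.8 TPM (2.35 ± 0.16), and Lgals3bp, a galectin-binding protein gene that went from 124 ± 9.51 to 426 ± 49.0 TPM (1.77 ± 0.09). Of 7 Clca genes 5 rose (adjusted p = 0.00499): Clca1, Clca2, Clca3b (0.72 ± 0.14), Clca4a and Clca4b. Of 32 Cyp genes 12 fell and 5 rose (median -0.19, adjusted p = 0.00043 for lower calls); Cyp2d22 (-0.99 ± 0.10) and Cyp2d34 (-0.92 ± 0.13) fell, while Cyp2j6 (0.66 ± 0.08), Cyp2c65, Cyp2c66, Cyp4f14 and Cyp4f40 rose. Of 10 tested Hoxa symbols, which include the antisense transcript Hoxa11os (-1.16 ± 0.20, beside Hoxa11 at 0.09 ± 0.20, with reads that mix unless strand is used), 7 fell (adjusted p = 0.000239), among them Hoxa9 (-0.68 ± 0.14), while the fitted values of all 8 tested Hoxb2 to Hoxb9 genes were above 0 (median 0.47), with Hoxb7 (0.92 ± 0.24, adjusted p = 0.0272) passing and the other 7 not. The Hoxa, Clca and Lgals medians kept their sign in both scalings, and so did the Cyp median (-0.29 in the scaling without mitochondrial transcripts).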
